A study of Homo sapiens with 6 samples.

How the data were processed

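Gene expression was measured in human dermal fibroblasts on 1-colour, biotin-labelled whole-transcript microarrays, with 3 arrays of cells given a control microRNA inhibitor and 3 of cells given a miR-29a inhibitor. The titles of the control arrays read 'ctr miRNA', and the name control inhibitor follows the treatment protocol. Per the labels' protocols, total RNA was extracted with Trizol and a miRNeasy kit, and sense-strand cDNA was made from 250 ng of it with the Ambion WT Expression Kit and labelled with the Affymetrix WT Terminal Labeling Kit. Per the submitters' processing notes, Affymetrix Expression Console 1.2 and GCRMA were used, in a role and order that the notes do not give. The values deposited by the authors are normalized log2 signals per probe set, between 2.94 and 14.8, with nearly equal quartiles in all arrays; that they are on a log2 scale was read from this range, they are not centred per gene, and no part of the scale is stated in the labels. The genome build and the processing options are not given in the sources used here. GCRMA in general subtracts a background modelled from probe sequence and combines the probes of a probe set, and background treatment affects differences at low signal most. Detection calls were not used here. The labels call the replicates biological without saying whether they were separate cultures or donors, so p-values measure the spread between these samples. No processing or hybridisation batch was stated in the labels.

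Of the 33297 probe sets, 21214 were listed in the platform annotation given with the series, 19460 with exactly 1 gene symbol and 1754 with several; 12083 were not listed and are unnamed here. Gene numbers of 19429 single-symbol probe sets matched the RefSeq gene table of the GRCh38.p14 assembly, which left every symbol as it was. No coordinates are given, since the array annotation names no build. A probe set with several symbols was never used to name a gene. For a gene with more than 1 single-symbol probe set (769 genes), list tests and named members used the one with the highest mean over all 6 arrays. There were 974 probe sets that shared all 6 values with another probe set; these were kept as in the table. No 2 arrays had more than 8 equal values, so none was a duplicate.

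The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates) on the deposited log2 values of all 33297 probe sets, with Benjamini-Hochberg adjustment over all of them and a threshold of 0.05. The SE is the moderated standard error. A fold is 2 raised to the log2 change, on the authors' normalized scale. The tests, the 21 gene lists (349 genes, 330 measured), the rule for named genes and the alternatives were chosen before the data were examined, except where stated. For each list, camera tested whether it shifted against all other genes, with a preset correlation of 0.01 between genes and adjustment over the lists; camera with an estimated correlation and fry were alternatives. The preset correlation is lenient when genes of a list vary together between arrays. Other splits of the same 6 arrays gave up to 6 lists past the threshold. Each of those splits still carries part of the difference between the groups, so that count does not measure how lenient the preset is. Per list, genes were also adjusted over the list alone. fry called 9 lists by direction and 19 in either direction. Random lists (10000 per list) were matched on mean level. The lists covered DNA demethylation and methylation enzymes, reported miR-29 targets in and outside the matrix, collagen processing, matrix proteases, the TGF-beta and myofibroblast response, cell cycle, p53 targets, interferon response, inflammation, cholesterol synthesis, endoplasmic reticulum stress, microRNA processing, housekeeping genes, and markers of fibroblasts and 6 other cell types. They were written from general knowledge, and the target lists include reports from other tissues.

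Named genes followed this rule: the 10 largest rises and 10 largest falls among single-gene probe sets past the threshold with no overlap between groups; every measured DNA demethylation and methylation gene; at most 4 members of each other list, those past the threshold first and then by smallest p; and ACTB, GAPDH and TBP.

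On simulated data for this comparison (33297 probe sets with the real means and spreads, 200 of them changed), limma recovered 59.9% of 1.5-fold and 89.0% of 2-fold changes, and 4.5% of calls were false. On 18417 genes, camera with the preset correlation found a list of 20 genes raised by 0.3 in 100% of simulations and called 2.8% of unchanged lists at p under 0.05, camera with the estimated correlation 100% and 0.5%, and fry 100% and 4.4%. These simulations drew genes independently of each other.

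Alternatives were other scalings, filters, moderation settings and thresholds, array weights, a replicate block and leaving out each array. A search of 3' UTRs for miR-29 seed matches was intended but was not run, because transcript sequences were not used here.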

Results

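The data were gene expression profiles of human dermal fibroblasts, the collagen-producing cells of the skin's connective tissue, cultured from skin and transfected with an inhibitor of a microRNA. A microRNA is a short RNA that lowers the level and translation of transcripts that pair with it. An inhibitor is a modified oligonucleotide that binds the mature microRNA and blocks it. Cells received 90 nM of an inhibitor of miR-29a or of a control inhibitor for 15 h, and RNA was taken after a further 48 h in fresh serum-containing medium, by the treatment protocol; the series' design text gives the treatment as 48 h. There were 6 arrays, 3 per group, each labelled as a separate biological replicate. The table held 33297 probe sets as log2 signals, of which 19460 carried exactly 1 gene symbol and represented 18417 genes. The medians of the arrays were 7.14, 7.15 and 7.10 for control replicates 1 to 3 and 7.14, 7.15 and 7.14 for inhibitor replicates 1 to 3. Pairs of arrays of the same group correlated at 0.996 to 0.997 across probe sets, and pairs from different groups at 0.995 to 0.996. The first principal component held 27.3% of the variance and placed the 3 control arrays on one side (-17.3 to -11.0) and the 3 miR-29a inhibitor arrays on the other (10.7 to 15.8). The number of arrays, 3 per group, limits the precision of every value below.

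The only comparison in the design asked which transcripts changed when miR-29a was inhibited. The mature microRNA itself is not measured by these probe sets. The probe set of its precursor gene, MIR29A, had a log2 signal of 4.95 ± 0.21 (SD, n = 3) in the control group and 4.97 ± 0.07 (SD, n = 3) with the inhibitor (limma, adjusted p = 0.97).

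With the miR-29a inhibitor, 174 of the 33297 probe sets changed, 87 upward and 87 downward (limma, adjusted p under 0.05). The balance moved with the scaling, to 108 upward and 89 downward after quantile normalization and to 57 and 74 after centring each array on its median. The 174 probe sets covered 146 named genes, 70 higher and 76 lower. The changes were small: 54 of the 174 reached 1.5-fold and 7 reached 2-fold, and the median absolute change was 0.50 on the log2 scale. The largest rise was that of TXNIP, which encodes an inhibitor of thioredoxin and a brake on glucose uptake. Its level was 3.44-fold higher (log2 change 1.78 ± 0.16, SE). CXCL8, the neutrophil chemokine interleukin-8, rose 2.79-fold (1.48 ± 0.20, SE), and PTGS2, the inducible cyclooxygenase, rose 1.82-fold. The other genes with the largest rises were FER1L6 (2.34-fold), TFPI2, a serine protease inhibitor (1.98-fold), CLDN1, a tight junction protein (1.96-fold), ELN, elastin (1.86-fold), NRG1, a growth factor of the epidermal growth factor family (1.78-fold), SCML2, a Polycomb-group protein (1.73-fold), and MMP16, a membrane-bound metalloproteinase (1.73-fold). Another probe set of NRG1 gave a smaller log2 change, 0.49 against 0.83, and did not pass (adjusted p = 0.096).

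The probe set that fell most, 3.06-fold, has no gene name here. It is 1 of 22 unnamed probe sets among the 174, and array control probe sets were not told apart from genes among the unnamed ones. Among named genes the largest falls were those of ACTG2, smooth muscle gamma-actin, at 2.11-fold lower (log2 change -1.07 ± 0.11, SE), and WFDC1, a small secreted protein, at 2.09-fold lower (-1.06 ± 0.07, SE). RNY1, a small non-coding Y RNA, was 1.85-fold lower, but near-identical copies in the genome make its signal uncertain. CNTN1, a neural adhesion protein, was 1.80-fold lower, and ENTPD1, an ectonucleotidase, was 1.75-fold lower. GCNT4 was 1.73-fold, FMOD 1.67-fold, CXCL14 1.62-fold, SLC1A1 1.61-fold and ENPEP 1.56-fold lower. FMOD encodes the collagen-binding proteoglycan fibromodulin, CXCL14 a chemokine, SLC1A1 a glutamate transporter and ENPEP an aminopeptidase. In all 174 probe sets the 3 inhibitor arrays lay entirely above or entirely below the 3 control arrays. Among all probe sets this held for 19.1%, against 10% by chance. When any single array was left out, limma called 0 probe sets (smallest adjusted p 0.0852 to 0.155), with 3137 to 3934 at an unadjusted p under 0.05 against 4048 with all arrays. All 174 kept an unadjusted p under 0.05 in each of those 6 limma fits, but they had been called on the same arrays. Their direction could not turn in those fits, since the groups overlap in none of them. Neither result is evidence that the calls are stable.

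**Figure D1:**
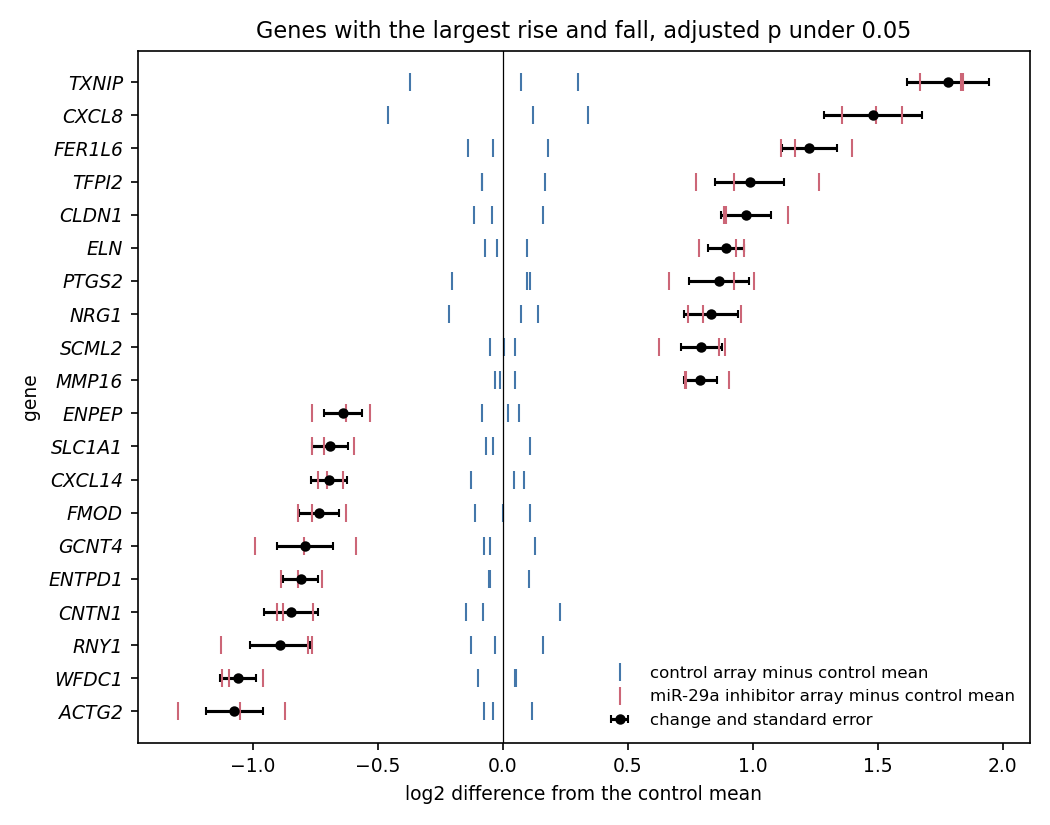
The 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold (rows). The horizontal axis is the log2 difference from the mean of the control arrays; coloured ticks are single arrays (blue control inhibitor, red miR-29a inhibitor), and black points with bars are the change and its standard error. TXNIP reaches 1.78 and ACTG2 -1.07, and in no row do blue and red ticks overlap.

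Genes of the DNA demethylation and methylation machinery were the first group examined, because the study may have been about the TET enzymes and TDG. If it chose them on these samples, their direction here is not independent evidence. TET1 and TET3, which oxidise 5-methylcytosine, and DNMT3A, a de novo DNA methyltransferase, rose with the inhibitor. TET1 went from a log2 signal of 8.08 ± 0.06 to 8.76 ± 0.14 (SD, n = 3 per group), a 1.60-fold rise (adjusted p = 0.037). TET3 was 1.57-fold higher (adjusted p = 0.031) and DNMT3A 1.34-fold higher (adjusted p = 0.037). TET2 had the largest difference of the group, 1.74-fold, with a larger spread (8.54 ± 0.22 against 9.34 ± 0.14, SD, n = 3 per group), and did not pass over all probe sets (adjusted p = 0.061). TDG, the glycosylase that removes oxidised methylcytosines, differed by 1.43-fold (adjusted p = 0.093), DNMT3B by 1.35-fold (adjusted p = 0.075) and GADD45B by 1.22-fold (adjusted p = 0.12). Each of these 7 genes had all inhibitor arrays above all control arrays.

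Of the 12 members measured, 3 rose, none fell and 9 did not pass over all probe sets. With p adjusted over the list alone, 7 were higher and none lower. The maintenance methyltransferase DNMT1 differed by -0.06 ± 0.06 (SE) on the log2 scale, its partner UHRF1 by -0.07 ± 0.08, and the base excision glycosylases MBD4 and SMUG1 by -0.04 ± 0.05 and 0.02 ± 0.06. GADD45A differed by 0.16 ± 0.07. As a set the list shifted upward against all other genes (median log2 change 0.35; camera, adjusted p = 4.2e-07). The call was lost with an estimated correlation between genes (adjusted p = 0.19 with an estimated correlation). Another probe set of TET2 gave a log2 change of 0.53, and another of UHRF1 gave 0.10, opposite in sign to the first.

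**Figure D2:**
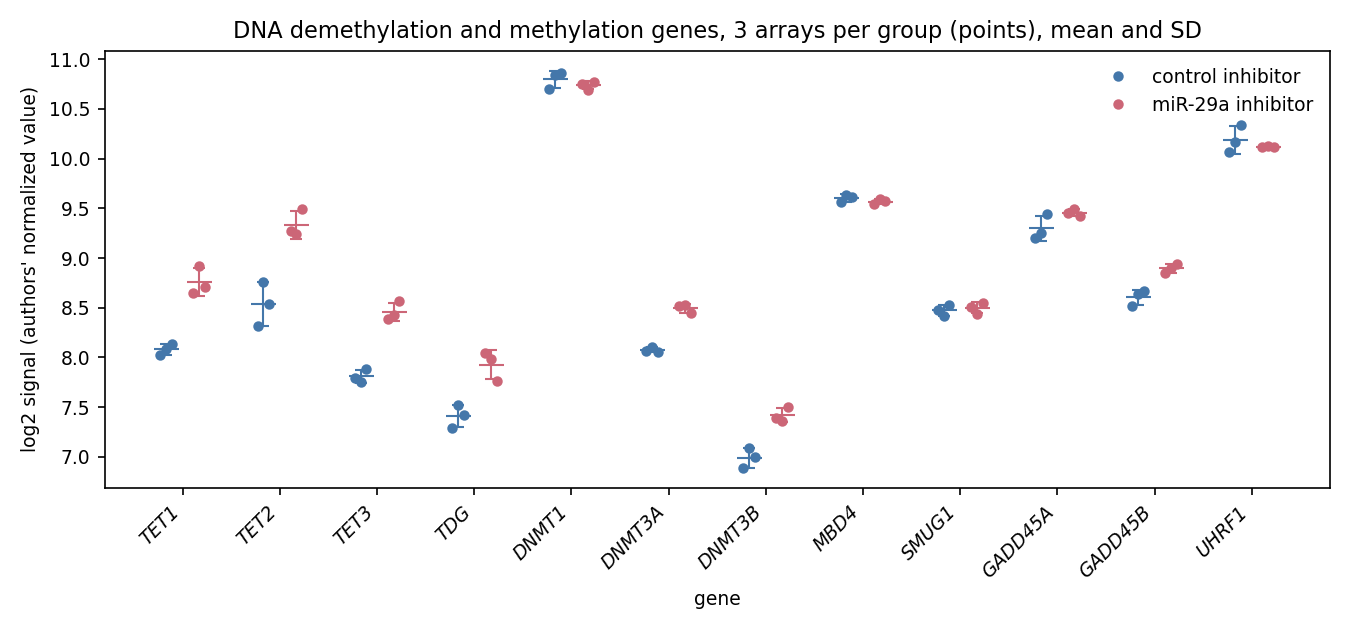
Log2 signal (vertical axis, the authors' normalized value) of the 12 DNA demethylation and methylation genes in each array; points are arrays, horizontal marks the group mean and bars the SD (n = 3 per group; blue control inhibitor, red miR-29a inhibitor). TET1, TET2, TET3, TDG, DNMT3A, DNMT3B and GADD45B show no overlap between the groups, while DNMT1, MBD4, SMUG1, GADD45A and UHRF1 do.

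Extracellular matrix genes that the literature reports as miR-29 targets formed the second group. Elastin (ELN, 1.86-fold), the fibrillar collagen chains COL5A2 (1.63-fold) and COL3A1 (1.49-fold) and the basement membrane collagen chain COL4A1 (log2 change 0.59 ± 0.06, SE) rose. COL1A1, a chain of type I collagen, rose 1.31-fold, from a log2 signal of 13.43 ± 0.03 to 13.82 ± 0.01 (SD, n = 3 per group). LOXL2, a collagen cross-linking oxidase, rose 1.52-fold. In total 7 of the 26 members rose, none fell and 19 did not pass over all probe sets. There were 16 higher and 1 lower adjusted over the list alone. The list shifted upward as a set (median log2 change 0.19; camera, adjusted p = 5.9e-14), and 23 of its 26 members had a positive change. That call was lost with an estimated correlation (adjusted p = 0.19 with an estimated correlation).

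A further list held other genes reported as miR-29 targets. Of 32 measured members, 4 rose (KDM5B, and TET1, TET3 and DNMT3A, which are also on the DNA demethylation and methylation list), none fell and 28 did not pass over all probe sets. KDM5B, a histone H3 lysine-4 demethylase, rose 1.36-fold from a log2 signal of 10.50 ± 0.04 to 10.94 ± 0.04 (SD, n = 3 per group). When adjusted over the list alone, 15 were higher and none lower. The list holds the TET genes and TDG, which the study itself may have put forward as targets from these cells, so those members are not independent evidence. The TET genes, TDG, DNMT3A and DNMT3B are all shared with the DNA demethylation and methylation list. Neither list was tested without the shared members. The list median was 0.15 on the log2 scale (camera, adjusted p = 2.8e-11), and the call held with an estimated correlation (adjusted p = 0.032 with an estimated correlation).

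Among 19 collagen processing and cross-linking genes, ADAMTS2, the procollagen N-proteinase, rose 1.38-fold, LOXL2 rose as given above, and 17 did not pass over all probe sets. The prolyl hydroxylase subunit P4HA1 differed by -0.32 ± 0.06 (SE) and the prolyl hydroxylase-related P3H3 by -0.30 ± 0.06, neither past the threshold. The list as a whole did not pass (camera, adjusted p = 0.34). Of 15 matrix proteases and their inhibitors, MMP16 rose 1.73-fold and 14 did not pass. MMP11 differed by -0.46 ± 0.09 (SE), MMP3 by 0.34 ± 0.08 and MMP10 by 0.20 ± 0.06, and the list did not pass (camera, adjusted p = 0.49). A second probe set of MMP16 gave a log2 change of 0.45 against 0.79 and did not pass (adjusted p = 0.054).

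Genes of the TGF-beta response and of contractile myofibroblasts shifted downward as a list (median log2 change -0.09; camera, adjusted p = 0.0016). That call was lost with an estimated correlation (adjusted p = 0.21 with an estimated correlation). None of the 20 measured members passed over all probe sets; adjusted over the list alone, 6 were lower and none higher. The 4 with the smallest p were contractile proteins: CNN1, calponin (-0.58 ± 0.09, SE), ACTA2, smooth muscle alpha-actin (-0.44 ± 0.09), TAGLN, transgelin (-0.48 ± 0.10), and MYL9, a myosin light chain (-0.21 ± 0.05). Markers of smooth muscle cells and pericytes shifted in the same direction (median -0.07, and -0.11 without control replicate 3; camera, adjusted p = 0.0076). This call too was lost with an estimated correlation (adjusted p = 0.19 with an estimated correlation), and it was lost among genes above the median level (adjusted p = 0.21). None of its 10 members passed over all probe sets, and 3 were lower adjusted over the list alone, all differing from the TGF-beta list's members: RGS5 (-0.37 ± 0.06, SE), LMOD1 (-0.45 ± 0.07) and SMTN (-0.31 ± 0.08). ABCC9, a potassium channel subunit, went the other way (0.20 ± 0.08, adjusted p = 0.35).

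Genes of cholesterol synthesis shifted downward as a list, and 4 of them fell. FDPS, farnesyl diphosphate synthase, was 1.48-fold lower, from a log2 signal of 10.74 ± 0.02 to 10.18 ± 0.09 (SD, n = 3 per group). CYP51A1, lanosterol demethylase, and IDI1, isopentenyl diphosphate isomerase, were each 1.32-fold lower, and DHCR7, which catalyses the last step of one branch of cholesterol synthesis, was 1.28-fold lower. Of the 17 measured members of the list, which covers cholesterol synthesis and genes controlled by the SREBP transcription factors, 4 fell, none rose and 13 did not pass over all probe sets. There were 15 lower and none higher adjusted over the list alone. The list median was -0.36 on the log2 scale (camera, adjusted p = 5.6e-16), and the call held with an estimated correlation (adjusted p = 0.035 with an estimated correlation). A second probe set of CYP51A1 gave a log2 change of -0.38 and did not pass (adjusted p = 0.12). Of the 22 genes fixed for the list, 5 had no single-gene probe set and were not analysed here.

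The lists of inflammatory and of interferon-response genes shifted upward (median log2 change 0.26 each; camera, adjusted p = 9.6e-08 and 2.9e-11). Both calls were lost with an estimated correlation (adjusted p = 0.19 with an estimated correlation for each). Of 21 inflammatory and NF-kB genes, CXCL8 (2.79-fold) and PTGS2 (1.82-fold) rose, none fell and 19 did not pass over all probe sets. Adjusted over the list alone, 7 were higher and none lower. CXCL1, a chemokine, differed by 0.48 ± 0.09 (SE), and IL1B, a cytokine, by 0.33 ± 0.06. Among 28 interferon-response genes, 27 had a positive change, but none passed over all probe sets. Of these, 13 were higher adjusted over the list alone. The 4 with the smallest p were DDX60 (0.36 ± 0.06, SE), IFI44 (0.46 ± 0.11), IFI35 (0.22 ± 0.05) and MX1 (0.51 ± 0.13), all induced by interferon. The SD of MX1 was 0.26 in the control group and 0.06 with the inhibitor.

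As a list, cell cycle genes shifted downward (median log2 change -0.13; camera, adjusted p = 4.8e-08). That call was lost with an estimated correlation (adjusted p = 0.21 with an estimated correlation), and the median was -0.09 without control replicate 3. RRM2, a subunit of the ribonucleotide reductase that makes deoxynucleotides, fell 1.40-fold and was the only member of 30 past the threshold over all probe sets. Adjusted over the list alone, 12 were lower and none higher, and 28 of the 30 had a negative change. TYMS, thymidylate synthase, differed by -0.36 ± 0.07 (SE), and the mitotic regulators AURKA and BUB1B each by -0.25 ± 0.05. Among 18 p53 targets none passed over all probe sets, and the list did not pass (camera, adjusted p = 0.20). CDKN1A, the cyclin-dependent kinase inhibitor p21, differed by 0.36 ± 0.05 (adjusted p = 0.054).

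In the endoplasmic reticulum stress list, 4 genes were higher and 5 lower adjusted over the list alone, none of 21 passed over all probe sets, and the list did not pass (camera, adjusted p = 0.16). The folding factors MANF (-0.32 ± 0.05, SE), PDIA6 (-0.26 ± 0.05) and PDIA4 (-0.28 ± 0.07) were lower in the inhibitor arrays and TRIB3, a pseudokinase, was higher (0.36 ± 0.08), none past the threshold. None of the 12 microRNA processing and silencing genes passed over all probe sets, and that list did not pass (camera, adjusted p = 0.20). XPO5, the exporter of microRNA precursors, differed by 0.25 ± 0.05.

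Among housekeeping genes, ACTB differed by -0.05 ± 0.05 (SE), GAPDH by -0.03 ± 0.05 and TBP by 0.06 ± 0.07, and none of 11 passed. The housekeeping list did not pass (camera, adjusted p = 0.20). Of 14 fibroblast markers, COL1A1 and COL3A1 rose as given above and 12 did not pass; the list did not pass (camera upward, adjusted p = 0.91), with a median of -0.03 and a mean of 0.03. Marker lists of keratinocytes, endothelial cells, melanocytes, immune cells and adipocytes did not pass (camera, adjusted p = 0.53, 0.20, 0.18, 0.91 and 0.93), nor did any of their members over all probe sets. The immune list was upward by camera with a median of -0.0034 and a mean of 0.02, and the adipocyte list downward with a median of 0.05 and a mean of -0.04. Both medians turned sign when single arrays were left out (-0.018 to 0.011 and -0.012 to 0.14). The endothelial receptor KDR had the largest difference among them (0.61 ± 0.11, SE, from a log2 signal of 6.01). In all, 9 of the 21 lists passed, 5 upward and 4 downward, and 2 of them passed with an estimated correlation.

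**Figure D3:**
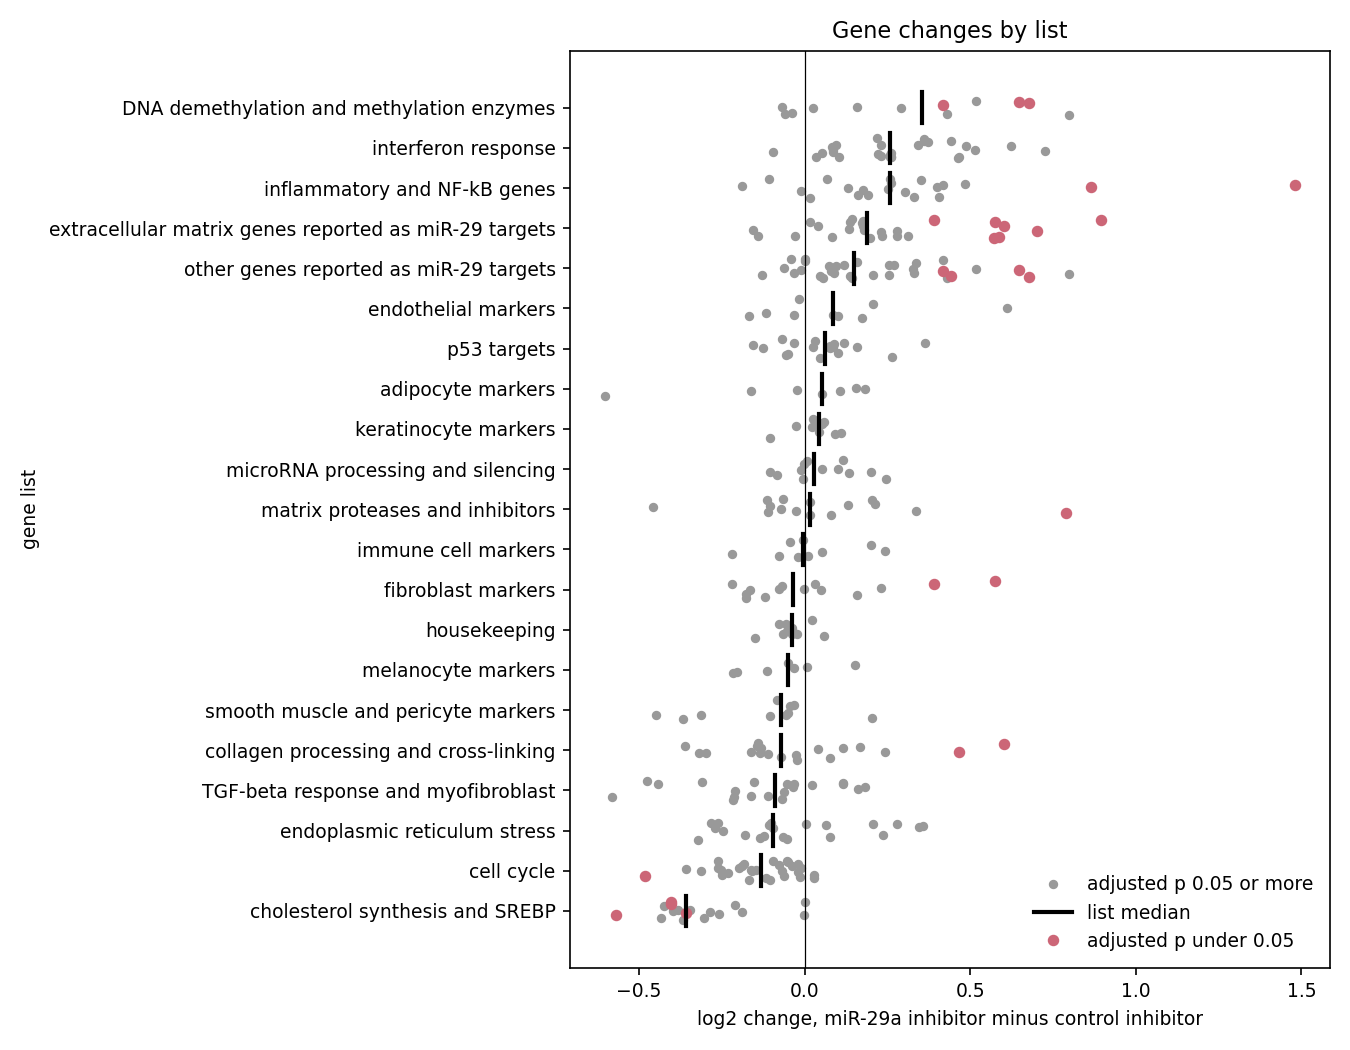
Log2 change (miR-29a inhibitor minus control inhibitor, horizontal axis) of every measured member of each of the 21 gene lists, ordered by list median (black bar); red points passed an adjusted p of 0.05 over all probe sets and grey points did not. The DNA demethylation and methylation list has the highest median (0.35) and the cholesterol list the lowest (-0.36).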

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

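Leaving out arrays within the 1-probe-set-per-gene analysis, and blocking it, were chosen after the data were seen. The number of changed probe sets depended on how many were tested and how the spread was estimated. It was 718 (337 higher, 381 lower) among probe sets above the median level, 632 (297 and 335) with 1 probe set per gene, 527 (243 and 284) with a level-dependent prior spread and 521 (245 and 276) when that prior was also robust. At an adjusted p of 0.1 it was 445 (218 and 227), and 54 (31 and 23) with a minimum of 1.5-fold. Centring each array on its median gave 131 (57 and 74), renormalizing by quantiles 197 (108 and 89) and weighting arrays 184 (89 and 95). The number was 0, both higher and lower, with the replicate block (limma; 3350 at an unadjusted p under 0.05) and in each of the 6 limma fits without 1 array (range 0 to 0; 3137 to 3934 at an unadjusted p under 0.05). With 1 probe set per gene the block gave 373 genes, 357 of them among the 632, and leaving out an array gave 220 (without miR-29a inhibitor replicate 2) to 350 (without control inhibitor replicate 2). Deviations from the group means correlated at -0.12, -0.053 and 0.0014 between arrays of the same number. In these deviations, no array correlated best with its own number in the other group. In the signals themselves, control replicate 2 and inhibitor replicate 3 did (0.9960 and 0.9962), and the other arrays did not. The labels state no pairing, so the numbers are not read as pairs, and whether they are stays open. All 174 kept their direction wherever they were tested, but only the other scalings could have turned it. Filters, moderation settings and the block leave each change as it was. Leaving out or weighting arrays cannot turn a change whose groups do not overlap. Signal over background was not assessed, so calls at low signal carry that limit. Of 21 lists, 9 passed with the replicate block, with fry, with gene means over probe sets and after quantile normalization, and 9 to 10 without single arrays. With an estimated correlation 2 passed, and the matrix target list and the DNA demethylation and methylation list were lost (adjusted p = 0.19 for each). The endoplasmic reticulum stress list passed only without control inhibitor replicate 1 (adjusted p = 0.045). Directions turned only for results that never passed: over the leave-one-out fits the immune marker list had an adjusted p of 0.65 to 0.87 and the adipocyte list 0.56 to 0.91, SMUG1 ranged from -0.0044 to 0.055, UHRF1 from -0.13 to 0.0082 and TBP from -0.0015 to 0.11. The medians of the melanocyte list (-0.10 to 0.0077) and of the matrix protease list (-0.016 to 0.035) also turned sign over those fits. Of 87 named genes recomputed, the 35 called kept their sign in every setting, which again only the other scalings could have turned. Among these 35 the call was lost most often for TFPI2 (9 of 14 settings) and for PTGS2, DHCR7 and CYP51A1 (8 of 14 each). Of the other 52, 31 passed in at least 1 setting, among them TET2 (adjusted p 0.0072 to 0.22), TDG (0.016 to 0.29) and DNMT3B (0.012 to 0.26). The search for seed matches in 3' UTRs was not run, and the pseudocount alternatives did not apply to log2 values.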

Other observations

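The tests in this part chosen only after the result was seen are those of level bias, of the TGF-beta programme and of immune cells, and the lists of small leucine-rich proteoglycans and of fatty acid synthesis; single genes named here outside the rule were chosen after their values were seen. Fatty acid synthesis genes were lower alongside the cholesterol genes. SCD and FASN are also on the fixed cholesterol and SREBP list, so the fatty acid list is not independent of that result. ELOVL6, a fatty acid elongase, fell by 0.61 ± 0.06 (SE) on the log2 scale and ACSS2, acetyl-CoA synthetase, by 0.49 ± 0.05. All 10 measured members were lower, 9 of them at an unadjusted p under 0.05, including FASN (-0.43 ± 0.07, adjusted p = 0.067) and ACLY (-0.32 ± 0.06, adjusted p = 0.092). The list gave a camera adjusted p of 2.0e-10 over the 4 added lists and 0.066 with an estimated correlation. Small leucine-rich proteoglycans, which bind collagen fibrils, were lower in 12 of 15 members. FMOD and PRELP fell (-0.74 ± 0.08 and -0.51 ± 0.06), and OGN (-0.63 ± 0.10, adjusted p = 0.060) and ECM2 (-0.60 ± 0.13, adjusted p = 0.14) did not pass. The camera adjusted p was 1.3e-06, and 0.066 with an estimated correlation. FMOD and PRELP had been seen to fall before this list was written, so it is not independent of them.

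Gene families defined by the letters at the start of the symbol were also scanned (330 families of at least 8 measured genes). Collagen genes (COL) had the smallest p: 35 of 44 were higher, 4 rose, and the camera adjusted p was 0.0050, but 0.96 with an estimated correlation. The 30 collagen genes outside the matrix target list were 23 higher and 7 lower, with a median log2 change of 0.06; none passed, and their camera p was 0.165. The families IFI and KDM shifted upward and TMED and HSP downward with the preset correlation, and no family passed with an estimated one. The medians of these 5 families and of the added lists kept their sign after quantile normalization and after median centring. Centring moves every change by the same amount, taking the median over all probe sets from 0.0019 to -0.011. That is too little to turn these medians, and the families were picked on the same arrays, so this gives no support.

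The rise of the reported miR-29 targets may reflect the loss of miR-29a repression that the design names, which stays a hypothesis. A level-dependent bias of the arrays predicts that genes of like level rise too; the matrix target list's median was 0.19, while 95% of random lists matched on level lay between -0.06 and 0.03. A general rise of matrix transcripts predicts that other matrix genes rise as well; 22 matrix genes outside the list had a median of -0.10, with 19 lower, and MFAP5 fell (-0.42 ± 0.05, SE), while MFAP2 went the other way without passing (0.37 ± 0.05, adjusted p = 0.054). The 30 collagen genes outside the list went the other way, 23 higher and 7 lower with a median of 0.06. Of those 30, only 11 were above the median level. The 2 sets overlap: COL6A1 (0.01), COL6A2 (-0.04), COL12A1 (-0.17) and COL14A1 (-0.24) are also among the 22 matrix genes. LUM, DCN and BGN, also among the 22, are on the list of small leucine-rich proteoglycans too. The fall of that list and that of the 22 are therefore not independent. A smaller rise among collagen genes stays open. Activation of the TGF-beta programme predicts a rise of its targets, whose median was -0.089, with 7 lower and none higher at an unadjusted p under 0.05. Differences between culture wells or hybridisations stay open, since the labels give no batch.

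The fall of the cholesterol list is not what level-dependent bias predicts: its median was -0.36, against -0.07 to 0.03 for 95% of matched random lists. INSIG1, which restrains SREBP activation, is a reported miR-29 target and also a member of the cholesterol list. Its log2 change was 0.00 ± 0.05 (SE). Because it is on both lists, which moved in opposite directions, this value does not show whether INSIG1 took part. A surplus of sterols sensed by the cells is a candidate explanation that predicts a rise of liver X receptor targets. Their median was -0.052; ABCA1 was higher (0.16 ± 0.05) and NR1H3 (-0.26 ± 0.08) and SMPDL3A (-0.24 ± 0.09) lower at an unadjusted p under 0.05, so this stays undecided. Cell density and growth were not measured here.

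The rise of the interferon and inflammatory lists was not set by 1 array: the lowest list median in any leave-one-out fit was 74.8% of that over all arrays. Immune cells in the inhibitor cultures predict that their markers rise together, and 1 of 9 (CD14, 0.24 ± 0.07, SE) was higher at an unadjusted p under 0.05. Of the other myeloid markers on the list, those with the smallest p were CD68 and CSF1R. CD68 differed by -0.22 ± 0.07 (limma, unadjusted p = 0.023) and CSF1R by 0.20 ± 0.09 (limma, unadjusted p = 0.062). Only 1 of the 9 markers lay above the median level, which limits what the list can show. An innate response to the inhibitor oligonucleotide itself might differ between the inhibitor sequences; the only values at hand are the rises themselves (list medians of 0.26 each), so it cannot be set apart from an effect of miR-29a loss.

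The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split was the only 1 of the 10 with as many changed probe sets (174, highest other 1), raised ones (87, highest other 1) or lowered ones (87, highest other 1); since the direction of another split is arbitrary, its calls were counted both ways, and a single probe set in 1 split gives both of these highest values. It was also the only 1 with as many lists past the threshold (9, highest other 6). The same held for the camera p of the matrix target list (5.6e-15, smallest other 2.5e-06), of the DNA demethylation and methylation list (1.4e-07, smallest other 0.0012) and of the cholesterol list (2.6e-17, smallest other 8.2e-05).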
